A study of Rattus norvegicus with 25 samples.

How the data were processed

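Total RNA from the esophageal epithelium of 25 male F344 rats was measured on 1-colour (Cy3) Agilent rat gene expression arrays, with 1 array per rat and 5 rats in each of 5 groups. Per the labels, RNA was prepared with TRIzol, quantified by spectrophotometer, amplified linearly and labelled with a commercial kit. Doses, routes and times of treatment are not given in the sources used here. The arrays sat on 4 slides, as the array files record.

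The array files hold scanner values as fluorescence intensity per the file headers, background-subtracted and detrended within each array and not normalized between arrays. Those headers name Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name version 10.7. The deposited value table of 30507 probes is on a log2 scale. Each of its columns followed the log2 processed signal of its array (lowest r over probes 1, as rounded), with the array's 75th percentile near 0. No column of either source belonged to samples outside the series (0 columns).

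The main values were computed from the scanner files. Spots that the scanner software called non-uniform or population outliers were dropped, the log2 processed signals of a probe's spots were averaged, and the 75th percentile of each array was subtracted. Of 30367 non-control probes on 58717 spots, 18355 matched 1 gene symbol through their RefSeq accession, 12012 matched none and 0 matched several. The table of names belongs to the GRCr8 assembly, whereas the array design was annotated on rn4, so it served for names only and no coordinates are given. A further 70 probes were left out because all their spots were dropped on some array. A probe was kept when it was well above background on at least 5 arrays, and each gene took its kept probe with the highest mean signal. Of 15443 named genes on the array, 12343 were tested; 2035 of these had several kept probes.

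Group means were fitted to all 25 arrays with limma 3.58.1 (20 residual degrees of freedom, prior degrees of freedom 3.09), and 10 pairwise contrasts were tested, two-sided, with Benjamini-Hochberg adjustment within each contrast at a threshold of 0.05. Each value given as log2 ± SE is the difference of group means with limma's moderated standard error, n = 5 rats per group. A fold is given as a lower bound where a gene was above background on no array of 1 of the groups; the bound uses, on those arrays, the lowest signal that was well above background, and the log2 value beside it is the fitted difference, which supports no more than the bound.

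Changes of 36 gene lists (541 listed genes, 452 tested, at least 4 per list) were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and limma's fry beside it, adjusted over the lists within a contrast. A list score was the mean, over a list's members in each rat, of the log2 value minus that member's mean over all 25 arrays. Scores were compared by two-sided exact permutation tests over all 252 assignments of 10 rats, adjusted over the lists, with 95% intervals obtained by inverting the test. Intervals of scores with slide as a block came from a linear model on the 25 rats. The lists for NF-κB targets and for the CXCR3 axis match themes that the study is known to have drawn from these samples, so they are not independent evidence.

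The groups, contrasts, lists, test and most alternatives were fixed before the data were examined. So was the rule for the genes named in each contrast: the 5 largest fitted rises and 5 largest fitted falls among called genes whose groups did not overlap, up to 4 called members of each described list (or up to 2 as values where none passed), and always Ccnd1, Mki67, Ptgs2, Nos2, Nfkb1, Rela, Cxcr3, Cxcl9, Cxcl10, Cxcl11, Cyp2a3 and Nqo1. Unplaced or provisional symbols were not named, and one gene withheld for evaluation is not reported here. Nfkb1 had no named probe, Ptgs2 was well above background on 0 arrays and Nos2 on 1, so these genes were not tested.

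The fits were tested on simulated data with each gene's own mean and residual spread, in which 100 of 12343 genes were set to change by each of 2 sizes. At 1 log2 unit, 74% of the genes set were recovered for NMBA against Control. At 2 log2 units it was 95%, and 6 unchanged genes were called at both sizes together. Over the comparisons this count was highest for alpha against NMBA, at 10 genes or 5.75% of its calls. Noise was drawn separately for each gene, without slide or array position, so these figures do not cover calls from such structure. For the tocopherol groups against NMBA, 68% were recovered at 1 log2 unit in each, and 96%, 97% and 95% at 2 log2 units for alpha, delta and gamma-enriched. For delta against alpha these were 67% and 93%, and for gamma-enriched against delta 71% and 95%. In the list test on simulated data, 0 of 35 unchanged lists were called in each contrast; simulated genes were not correlated, so this says nothing about calls due to correlated members.

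The alternatives were quantile normalization, normexp background correction (offset 50), the authors' value table, no filter or a filter on all 25 arrays, the mean of a gene's probes, slide as a fixed or a random block, a single slide, rat number as a block, a fit on only the groups compared, and leaving out each rat in turn. Chosen after seeing the data were normexp on median signals (mean signals are not in the scanner files), the slide column as a covariate, all probes as features, and fits without NMBA rats 2 and 3, without gamma-enriched rat 3 or without the array on slide 4. The random slide block had an estimated correlation of −0.0311. Rats sharing a number in different groups were not more alike than others (mean r −0.0498 over 50 pairs, from −0.584 to 0.529, with 12 pairs above 0.1), so rat number was used only as an alternative. For 25 arrays of 1 tissue, the number of rats per group limits the precision of each value. Calculations used R 4.3.3 (data.table, version 1.17.8) and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.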

Results

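Gene expression was measured in the esophageal epithelium of 5 groups of male F344 rats, each of 5 animals. One group ate a normal diet and received no carcinogen (Control). Another, on the same diet, received N-nitrosomethylbenzylamine (NMBA), a nitrosamine that induces esophageal tumours in rats. The other groups received NMBA together with a vitamin E preparation, namely alpha-tocopherol, delta-tocopherol or a mixture enriched in gamma-tocopherol. These tocopherols differ in the number and place of methyl groups on the chromanol ring. The slides held the groups unevenly. Slide 1 carried alpha rats 1 to 5 and delta rats 1 to 3; slide 2 carried delta rats 4 and 5, gamma-enriched rats 1 to 5 and Control rat 1. Slide 3 carried Control rats 2 to 5 and NMBA rats 1 to 4, and slide 4 carried NMBA rat 5. Only Control rat 1 therefore links the tocopherol slides to those of the NMBA rats.

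Between 70.6% (NMBA rat 3) and 79.8% (alpha rat 3) of spots were well above background, and NMBA rat 2 lay close to the lowest at 70.9%. The 75th percentile of signal ran from 3088 in alpha rat 1 to 8096 in gamma-enriched rat 2, with 0 saturated spots on the arrays. Rats of 1 group differed nearly as much as rats of different groups: the SD of the log2 difference between a pair of arrays had a median of 0.645 over 50 pairs within groups and 0.699 over 250 pairs between groups. The first 3 principal components held 23.9%, 14.2% and 13.8% of the variance.

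The comparison of NMBA with Control asks what the carcinogen changed in the epithelium. In NMBA rats, interferon-induced chemokines and T cell genes were higher, together with a gut hormone gene and a hair keratin gene. The incretin hormone Gip rose by 5.57 ± 0.34 log2 units (adjusted p = 3.64e-10), or 47.6-fold, and the hair keratin Krt82 by 3.64 ± 0.36, at least 4.68-fold. Cxcl10, Cxcl9 and Cxcl11, which are ligands of Cxcr3, a chemokine receptor of T cells, rose by 4.35 ± 0.53, 3.60 ± 0.51 and 3.25 ± 0.43, and Cxcr3 itself rose by 1.89 ± 0.42 (adjusted p = 0.0191). Cd27, a co-stimulatory receptor of T cells, rose by 3.82 ± 0.72, at least 4.85-fold. Among genes whose groups did not overlap, falls were found in the transcription factor Zbtb16 (−2.33 ± 0.42), the actin regulator Phactr3 (−2.17 ± 0.54), the glutamate receptor subunits Grik2 (−1.96 ± 0.39, at least 1.1-fold) and Gria2 (−1.81 ± 0.42), and the channel gene Pkd2l2 (−1.68 ± 0.29, at least 1.32-fold). In each of these genes except Cxcr3, every NMBA rat lay beyond every Control rat. With normexp background correction Gip stood at 3.58, Krt82 at 1.44 and Cd27 at 1.81, and Phactr3 (−1.08), Grik2 (−0.61), Gria2 (−0.51) and Pkd2l2 (−0.46) did not pass.

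In total 191 of 12343 genes changed between NMBA and Control, 161 higher and 30 lower, and 117 changed at least 2-fold. Groups did not overlap in 155 of the 191, and in 4.0% of all genes, against 0.794% by chance. Among DNA damage genes, the cell cycle inhibitor Cdkn1a rose by 0.79 ± 0.14, the alkylguanine repair gene Mgmt by 0.84 ± 0.16 and Btg2 by 0.69 ± 0.15. The proliferation gene Mki67 stood at −0.05 ± 0.32 and the cyclin Ccnd1 at 0.27 ± 0.17, neither past the test, while Ccne1 rose by 1.20 ± 0.30. Values that did not pass were also found for Rela (0.43 ± 0.23), the nitrosamine-activating Cyp2a3 (0.12 ± 0.39) and the oxidant-response gene Nqo1 (0.06 ± 0.14). Within slide 3 alone, Gip rose by 5.33, Cxcl10 by 4.20, Krt82 by 3.32, and Zbtb16 fell by 2.16. All 191 genes kept their sign within slide 3, where 31 genes were called. The rats on slide 3 also served to select the 191 genes, so the kept signs are no separate evidence. With slide as a fixed block 62 genes were called, and Cxcr3 (1.70), Btg2 (0.56), Gria2 (−1.58), Phactr3 (−2.08), Cd3d (1.87), Cd3e (1.92), Gzmb (2.14), Ciita (1.11), Ccne1 (0.85) and Bcl2a1 (1.1) no longer passed. The count fell to 115 without Control rat 1, 120 without Control rat 4, 115 without NMBA rat 1, 126 without NMBA rat 2 and 96 without NMBA rat 5, and rose to 297 without NMBA rat 4. Cdkn1a, at 0.55, did not pass with the mean of its probes.

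Of the 36 gene lists, 7 differed between NMBA and Control by camera and 6 by fry. The interferon list was higher by 0.94 log2 units (95% interval 0.66 to 1.23; adjusted p = 7.12e-19), with 8 of 24 members called and 19 adjusted over the list alone. Isg15 rose by 2.37 ± 0.30, Oas1a by 2.20 ± 0.37 and Irf7 by 1.29 ± 0.20. The T and NK cell list was higher by 1.26 (0.62 to 1.73; adjusted p = 1.08e-13), with 8 of 16 members called and 13 adjusted over the list alone, among them Gzmb (2.34 ± 0.45), Cd3d (2.24 ± 0.45), Cd8b (2.23 ± 0.42; 1.07 with normexp) and Cd3e (2.11 ± 0.43). The CXCR3 list, which is not independent evidence, was higher by 2.10 (1.56 to 2.58; adjusted p = 1.26e-06), with 4 of 6 members called and 4 adjusted over the list alone. The p53 and DNA damage list was higher by 0.31 (0.21 to 0.41; adjusted p = 3.58e-04), with 3 of 18 members called and 4 adjusted over the list alone. MHC class II genes were higher by 0.76 (0.31 to 1.21; adjusted p = 1.27e-07, but adjusted p = 0.155 with an estimated correlation). Of its 9 members 1 was called, the transactivator Ciita (1.20 ± 0.24), and 8 adjusted over the list alone.

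**Figure D1:**
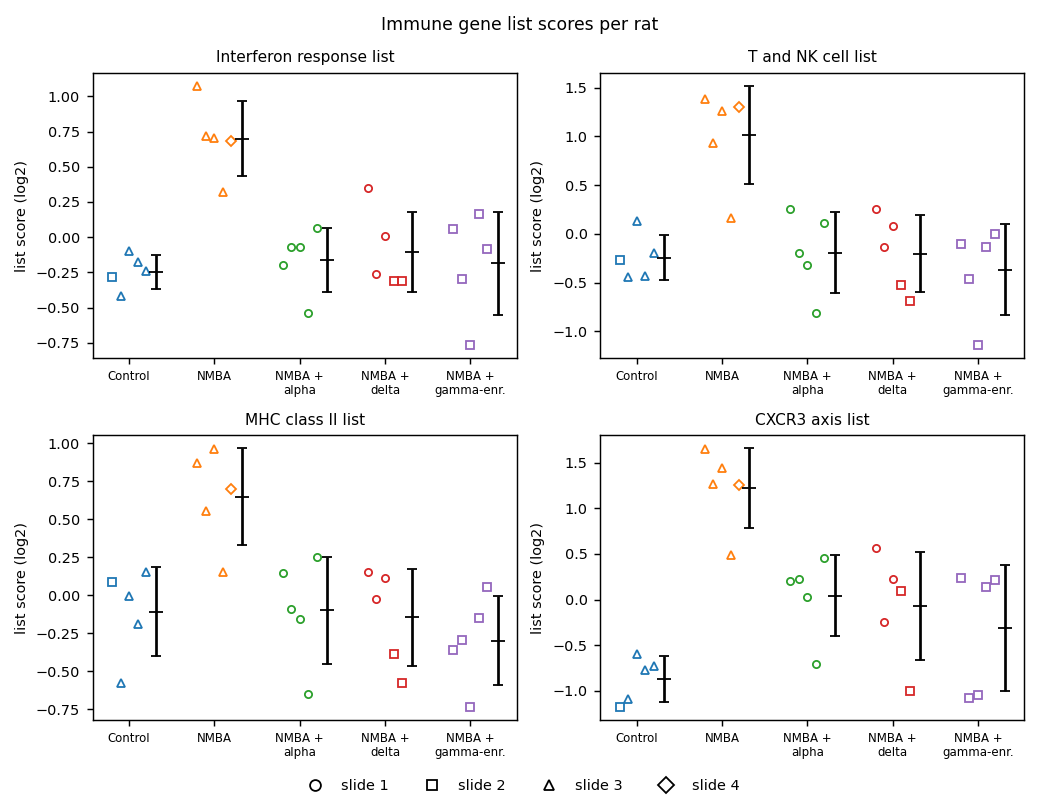
Scores of the interferon, T and NK cell, MHC class II and CXCR3 lists in each rat (points), with the mean and SD of each group (bars, n = 5). A score is the mean over members of the log2 value minus the member's mean over all 25 arrays. All NMBA scores lie above all Control scores in each list, and the means of the tocopherol groups lie lower than that of NMBA.

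Fibroblast matrix genes stood at −0.52 in NMBA (−1.05 to −0.15), with all 15 members negative and 0 called or adjusted over the list alone (camera adjusted p = 3.01e-05, but adjusted p = 0.582 with an estimated correlation). NMBA rat 5 stood apart, with a score of −1.08, and without it the shift was −0.28. Postn stood at −1.11 ± 0.35 and Col1a1 at −0.74 ± 0.32. Nerve and Schwann cell genes were at −0.58 (−1.09 to −0.03), with 0 of 8 called or adjusted over the list alone (camera adjusted p = 0.0127, but adjusted p = 0.387 with an estimated correlation). The interferon, T and NK cell, MHC class II, CXCR3, p53, fibroblast and immediate early scores of NMBA and Control rats did not overlap, which gives the smallest exact permutation p that 5 against 5 allows, 0.00794 (adjusted p = 0.0408). The immediate early and heat shock list, at 0.25 (0.15 to 0.36), was not called by camera. With slide as a block, interferon stood at 0.939 (0.53 to 1.35), T and NK cells at 1.18 (0.575 to 1.78), and MHC class II at 0.792 (0.338 to 1.25). The blocked shifts of the others were CXCR3 at 2.01 (1.24 to 2.78), p53 at 0.275 (0.163 to 0.388), fibroblast matrix at −0.305 (−0.921 to 0.311) and nerve at −0.554. NF-κB targets, also not independent evidence, stood at 0.23 (−0.50 to 0.94), with 1 of 16 called, Bcl2a1 (1.26 ± 0.29; not past the test with the block), and 4 adjusted over the list alone; the shift moved to 0.0854, 0.38, 0.38 and 0.0953 without Control rats 2 and 3 and NMBA rats 4 and 5.

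The comparison of each tocopherol group with NMBA asks whether the preparation altered the carcinogen's changes. Interferon, T and NK cell, MHC class II and CXCR3 lists were lower by camera in the alpha-tocopherol rats than in rats given NMBA alone, but with an estimated correlation adjusted p was from 0.146 to 0.291. The chemokines Ccl12 and Ccl1 fell by 3.37 ± 0.61 and 2.75 ± 0.47 log2 units, the latter at least 3.03-fold. The cytotoxic protease Gzmb fell by 2.17 ± 0.45, the protease inhibitor Stfa3l1 fell by 2.10 ± 0.38 and the ficolin Fcnb fell by 2.09 ± 0.53. The CXCR3 ligands Cxcl11, Cxcl10 and Cxcl9 stood at −1.89 ± 0.43, −1.88 ± 0.53 and −1.85 ± 0.51, each past the test, while Cxcr3 at −1.45 ± 0.42 was not (adjusted p = 0.0524). Among genes whose groups did not overlap, the largest rises were the transcription factor Nfic (2.53 ± 0.31), the metabolic kinase Pdk4 (1.99 ± 0.52), Trib1 (1.75 ± 0.23), Rasd1 (1.59 ± 0.30) and the cohesin regulator Pds5a (1.57 ± 0.33). Normexp gave smaller values for Nfic (1.38), Trib1 (0.98), Pds5a (0.61), Ccl12 (−1.65) and Ccl1 (−0.80), and Pdk4 at 1.43 did not pass.

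Between alpha-tocopherol and NMBA, 471 genes changed, 160 higher and 311 lower. Camera called 6 lists, each of them lower. Interferon genes stood at −0.86 (−1.24 to −0.52; adjusted p = 3.81e-14, but adjusted p = 0.146 with an estimated correlation), with 11 of 24 called and 18 adjusted over the list alone. T and NK cell genes stood at −1.21 (−1.85 to −0.53; adjusted p = 4.55e-11, but adjusted p = 0.181 with an estimated correlation), with 8 of 16 called and 13 adjusted over the list alone. MHC class II genes stood at −0.75 (−1.23 to −0.28; adjusted p = 1.57e-06, but adjusted p = 0.291 with an estimated correlation), with 5 of 9 called and 8 adjusted over the list alone; Cd74 fell by 0.76 ± 0.18 and did not pass with quantile normalization (−0.57). The CXCR3 list stood at −1.18 (adjusted p = 0.00220, but adjusted p = 0.291 with an estimated correlation; 3 of 6 called, 5 adjusted over the list alone). NF-κB targets stood at −0.55 (−1.27 to 0.22; adjusted p = 0.00188, but adjusted p = 0.627 with an estimated correlation; 4 of 16 called, 7 adjusted over the list alone); neither list is independent evidence. Among NF-κB targets the adhesion gene Icam1 fell by 0.89 ± 0.19. Xenobiotic metabolism genes were at −0.31 (adjusted p = 0.0297, but adjusted p = 0.396 with an estimated correlation), with 0 of 16 called or adjusted over the list alone. Mki67 (−0.17 ± 0.32), Ccnd1 (0.25 ± 0.17), Rela (−0.48 ± 0.23), Cyp2a3 (−0.78 ± 0.39) and Nqo1 (−0.13 ± 0.14) did not pass. No slide holds both groups, and with slide as a fixed block 1 gene was called. The blocked shifts were −1.16 (−2.08 to −0.239) for interferon, −1.78 (−3.13 to −0.421) for T and NK cells, −1.54 (−2.56 to −0.515) for MHC class II and −1.42 (−3.15 to 0.317) for CXCR3, which camera no longer called (adjusted p = 0.0944). For NF-κB targets and xenobiotic genes they were −0.597 (−1.97 to 0.778) and −0.364 (−0.836 to 0.107), the latter no longer called (adjusted p = 0.247). The count fell to 282 without alpha rat 4, 271 without NMBA rat 1, 237 without NMBA rat 2 and 191 without NMBA rat 3.

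In delta-tocopherol rats the interferon, T and NK cell, MHC class II and CXCR3 lists were lower by camera than in NMBA, but with an estimated correlation adjusted p was from 0.228 to 0.260. Zbtb16, which NMBA had lowered, rose by 1.99 ± 0.42. Ccl12 fell by 2.30 ± 0.61, Cxcl9 fell by 2.20 ± 0.51, Cxcl11 fell by 1.98 ± 0.43, Gzmb fell by 1.98 ± 0.45 and Cd3d fell by 1.93 ± 0.45. Cxcr3 at −1.54 ± 0.42 narrowly passed, and Cxcl10 at −1.84 ± 0.53 narrowly did not (adjusted p = 0.0556). Beside Zbtb16, the largest rises among genes whose groups did not overlap were the myosin Myh3 (2.66 ± 0.70), Ctxn3 (1.81 ± 0.48), Gria2 (1.64 ± 0.42), which had also fallen with NMBA, and the mitotic gene Hmmr (1.50 ± 0.35). The cytotoxic gene Prf1 (−1.44 ± 0.39), the transcription factor Arid3b (−1.43 ± 0.24) and the channel gene Asic3 (−1.67 ± 0.43, at least 1.17-fold) fell as well; Asic3 stood at 0.64 with slide as a fixed block. Under normexp Ccl12 stood at −1.42 and Arid3b at −0.55, and Ctxn3 (1.43), Gria2 (0.36) and Asic3 (−0.40) did not pass.

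Between delta-tocopherol and NMBA, 307 genes changed, 58 higher and 249 lower. Interferon genes stood at −0.80 (−1.18 to −0.35; adjusted p = 1.64e-11, but adjusted p = 0.228 with an estimated correlation), with 8 of 24 called and 21 adjusted over the list alone. T and NK cell genes stood at −1.21 (−1.91 to −0.55; adjusted p = 2.69e-10, but adjusted p = 0.228 with an estimated correlation), with 8 of 16 called and 13 adjusted over the list alone. MHC class II genes stood at −0.79 (−1.27 to −0.30; adjusted p = 8.04e-07, but adjusted p = 0.260 with an estimated correlation), with 4 of 9 called and 8 adjusted over the list alone, and Cd74 fell by 0.94 ± 0.18 (−0.66 and not past the test with quantile normalization). The CXCR3 list, not independent evidence, stood at −1.29 (adjusted p = 0.00189, but adjusted p = 0.260 with an estimated correlation; 3 of 6 called, 5 adjusted over the list alone). NF-κB targets, likewise not independent, were at −0.37 (adjusted p = 0.0747), with 2 of 16 called and 3 adjusted over the list alone, and at −0.23 without NMBA rat 5. Cell cycle genes were higher at 0.24 (−0.15 to 0.61), with 24 of 30 positive and 0 called or adjusted over the list alone (adjusted p = 0.00376, but adjusted p = 0.779 with an estimated correlation), and the shift moved to 0.16 without NMBA rat 1 and 0.36 without NMBA rat 5. Squamous differentiation genes were lower at −0.24 (adjusted p = 0.0432, but adjusted p = 0.779 with an estimated correlation), with 1 of 16 called, the keratin Krt4 (−0.69 ± 0.15), and 6 lower and 1 higher adjusted over the list alone. Blocked by slide, that shift turned to 0.231 (−0.312 to 0.774) and Krt4 to 0.01; with quantile normalization Krt4 at −0.18 did not pass. With the block, interferon stood at −0.966 (−1.78 to −0.149), T and NK cells at −1.52 (−2.72 to −0.311), MHC class II at −1.36 (−2.27 to −0.451), CXCR3 at −1.28 (−2.82 to 0.261) and cell cycle at 0.660 (−0.187 to 1.51), with 1 gene called. Mki67 (0.11 ± 0.32), Ccnd1 (−0.14 ± 0.17), Rela (−0.32 ± 0.23), Cyp2a3 (−0.87 ± 0.39) and Nqo1 (−0.21 ± 0.14) did not pass. The count fell to 32 without delta rat 2, 102 without delta rat 3, 158 without delta rat 4, 156 without delta rat 5, 23 without NMBA rat 1, 16 without NMBA rat 2 and 13 without NMBA rat 3, and rose to 566 without NMBA rat 4.

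In rats given the gamma-enriched mixture the interferon, T and NK cell, MHC class II and CXCR3 lists were lower than in NMBA by camera, but adjusted p was 0.311 for each with an estimated correlation. In all, 196 genes were higher and 909 lower, more than in the other comparisons, and the median of all genes tested stood at −0.10. Ccl12 fell by 2.76 ± 0.61, the coagulation factor F10 fell by 2.54 ± 0.55 (at least 3.38-fold), Ccl1 fell by 2.48 ± 0.47, Cxcl11 fell by 2.42 ± 0.43 and Cd3d fell by 2.38 ± 0.45. Sslp1l1 fell by 2.68 ± 0.52, at least 2.05-fold, but stood at 0.38 with slide as a fixed block. Zbtb16 rose by 2.13 ± 0.42, with groups that overlapped. Among genes whose groups did not overlap, the largest rises were Pds5a (1.80 ± 0.33), Parpbp (1.69 ± 0.52), Nfic (1.57 ± 0.31), the replication gene Dbf4 (1.51 ± 0.36) and Pkn2 (1.42 ± 0.36), the last at −0.02 with the block. In the normexp fit Pds5a stood at 0.59, Nfic at 0.67, Dbf4 at 0.99, Ccl12 at −1.62, F10 at −1.103, Ccl1 at −0.98 and Sslp1l1 at −0.85, and Parpbp (0.58) did not pass. Of the squamous differentiation list, which camera did not call (−0.30; adjusted p = 0.0796), the keratins Krt4 and Krt13 fell by 0.81 ± 0.15 and 0.81 ± 0.19 and the cornified envelope genes Cnfn and Tgm1 by 0.77 ± 0.18 and 0.59 ± 0.15. These 4 genes stood at −0.14, −0.05, −0.007 and −0.22 with slide as a block, none past the test, and camera's direction for the list turned. Quantile normalization also ended their calls, at −0.18, −0.098, −0.16 and −0.26.

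Interferon genes in the gamma-enriched group stood at −0.89 relative to NMBA (−1.41 to −0.42; adjusted p = 1.90e-09, but adjusted p = 0.311 with an estimated correlation), with 13 of 24 called; adjusted over the list alone, 18 were lower and 1 higher. T and NK cell genes stood at −1.38 (−2.08 to −0.63; adjusted p = 4.22e-09, but adjusted p = 0.311 with an estimated correlation), with 12 of 16 called and 12 adjusted over the list alone. MHC class II genes stood at −0.95 (−1.38 to −0.48; adjusted p = 1.27e-06, but adjusted p = 0.311 with an estimated correlation), with 8 of 9 called and 8 adjusted over the list alone; Ciita fell by 1.34 ± 0.24 and Cd74 fell by 1.06 ± 0.18. The CXCR3 list, not independent evidence, stood at −1.53 (−2.51 to −0.69; adjusted p = 0.00341, but adjusted p = 0.311 with an estimated correlation), with 4 of 6 called and 4 adjusted over the list alone. Cxcl9 fell by 2.26 ± 0.51, Cxcl10 fell by 2.17 ± 0.53 and Cxcr3 fell by 1.70 ± 0.42. NF-κB targets, likewise not independent, stood at −0.58 (−1.15 to 0.02; adjusted p = 0.0144, but adjusted p = 0.836 with an estimated correlation), with 4 of 16 called, among them Il1b (−1.97 ± 0.43) and Icam1 (−1.14 ± 0.19), and 6 adjusted over the list alone. Cell cycle genes were higher at 0.21 (adjusted p = 0.0182, but adjusted p = 0.939 with an estimated correlation), with 1 of 30 called, Bub1 (1.24 ± 0.36), and 0 adjusted over the list alone; the shift moved to 0.12, 0.13 and 0.33 without NMBA rats 1, 2 and 5. The exact permutation test separated the interferon, T and NK cell, MHC class II, CXCR3, Langerhans cell (−0.91, −1.58 to −0.38) and xenobiotic (−0.35, −0.61 to −0.12) scores, each at an adjusted p of 0.0476. In alpha and delta against NMBA the smallest adjusted exact p were 0.0952 and 0.114. These adjusted values depend on how many lists reach the smallest exact permutation p, 0.00794, so they do not rank the preparations. In alpha the interferon and CXCR3 scores (at most 0.0644 and 0.459) did not overlap those of NMBA (at least 0.323 and 0.490), whereas in delta they did.

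With slide as a block, the gamma-enriched shifts from NMBA were −0.843 (−1.6 to −0.0903) for interferon, −1.28 (−2.39 to −0.168) for T and NK cells, and −1.18 (−2.01 to −0.338) for MHC class II. They were −1.14 (−2.56 to 0.285) for CXCR3, −0.174 (−1.3 to 0.952) for NF-κB targets, no longer called by camera (adjusted p = 0.0855), and 0.574 (−0.208 to 1.35) for cell cycle genes. The gene called with the block in each tocopherol group against NMBA was Plpp1, named after its values were seen, at 3.42 ± 0.41, 3.62 ± 0.37 and 3.61 ± 0.34 for alpha, delta and gamma-enriched. Without the block it stood at 0.31, 0.41 and 0.26 (± 0.46 each), and Control rat 1 had a far lower value (−1.92) than the other Controls. The block sets the slides level through that rat alone, so the Plpp1 calls rest on its value. Mki67 (0.38 ± 0.32), Ccnd1 (−0.21 ± 0.17), Rela (−0.50 ± 0.23), Cyp2a3 (−0.79 ± 0.39) and Nqo1 (−0.07 ± 0.14) did not pass between gamma-enriched and NMBA. The sum of both directions fell to 648 without gamma-enriched rat 1, 608 without gamma-enriched rat 2, 546 without NMBA rat 1 and 607 without NMBA rat 2.

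Alpha and delta shared 139 genes lower than NMBA, alpha and gamma-enriched 139, and delta and gamma-enriched 173. Independent lists would share 6.27, 22.9 and 18.3, a figure that leaves out the NMBA rats common to both lists. Simulations without effects gave 0 in each pair. The simulated groups had NMBA's own means, so few genes could be called, and arrays were exchanged across slides. Their overlap of 0 therefore does not show what shared NMBA rats or slides would give. With separate NMBA rats for the 2 preparations of a pair, and so fewer rats, medians over 10 splits were 2, 2.5 and 0, against 0.0193, 0.237 and 0 for independent lists of those sizes. Of the 191 genes that NMBA changed, 181, 180 and 180 moved the opposite way in the alpha, delta and gamma-enriched groups (94.8%, 94.2% and 94.2%), by a median of 0.56, 0.61 and 0.53 log2 units against a median NMBA change of 1.14. Because both comparisons share the NMBA rats, simulated groups with no effect gave means of 61.0%, 60.4% and 61.1%. The central 95% of the simulations reached up to 84.2%, 83.4% and 83.1%, and some lay higher. When some NMBA rats selected the genes and the others were compared, medians over 10 splits were 85.9%, 84.6% and 85.1%, from lows of 63.0%, 67.3% and 73.8%. The opposite change itself passed the test in 60, 57 and 87 of the genes, while 35, 19 and 30 still differed from Control. Genes higher with NMBA and lower again with the preparation numbered 56, 51 and 79. Independent sets would give 4.06, 3.25 and 11.9, and the simulations gave at most 1, 3 and 1, with the same limits as for the overlaps. With slide as a fixed block, 79.0%, 80.7% and 91.9% of the 62 genes called moved the opposite way.

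**Figure D2:**
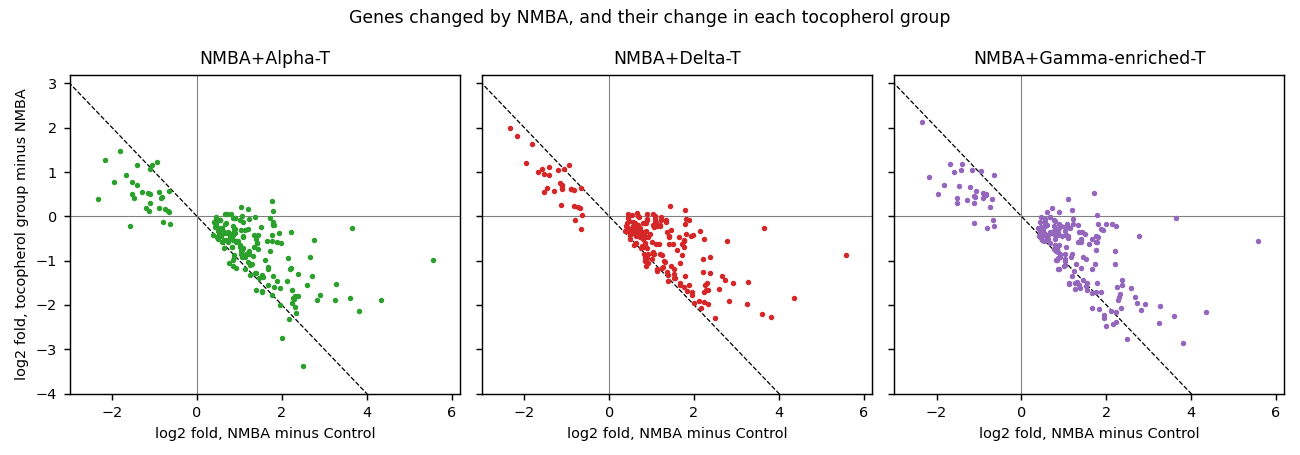
Log2 change of the 191 genes that NMBA changed, NMBA minus Control on the horizontal axis and each tocopherol group minus NMBA on the vertical axis; each point is a gene and the dashed line marks a full return to Control. Between 94.2% and 94.8% of the points lie on the opposite side of 0.

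Each tocopherol group was also compared with Control, which asks what remained changed. Gip and Krt82 stayed high in each of the 3 groups. Gip was higher by 4.58, 4.69 and 5.01 (± 0.34 each) and Krt82 by 3.39, 3.38 and 3.61 (± 0.36 each) in alpha, delta and gamma-enriched, the latter at least 3.91-fold, 3.89-fold and 4.59-fold. With slide as a block these were 6.29, 6.01 and 5.75 for Gip and 4.96, 4.47 and 3.99 for Krt82, and with normexp 2.58, 2.64 and 3.01 for Gip and 1.30, 1.25 and 1.28 for Krt82. The transporter ATPase Atp13a5 rose by 2.24, 2.21 and 2.31 (± 0.29 each, and 1.19, 1.13 and 1.07 with normexp), and the thymidylate synthase Tyms by 0.67, 0.78 and 0.69 (± 0.14 each). Atp13a5 was also called between NMBA and Control, whereas Tyms was not. Cxcl10 remained above Control by 2.46 ± 0.53 with alpha and 2.51 ± 0.53 with delta (1.97 with normexp, not past the test), and at 2.18 with gamma-enriched did not pass (adjusted p = 0.0574). In all, 101, 24 and 78 genes differed from Control, of which 79, 21 and 45 were higher.

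**Figure D3:**
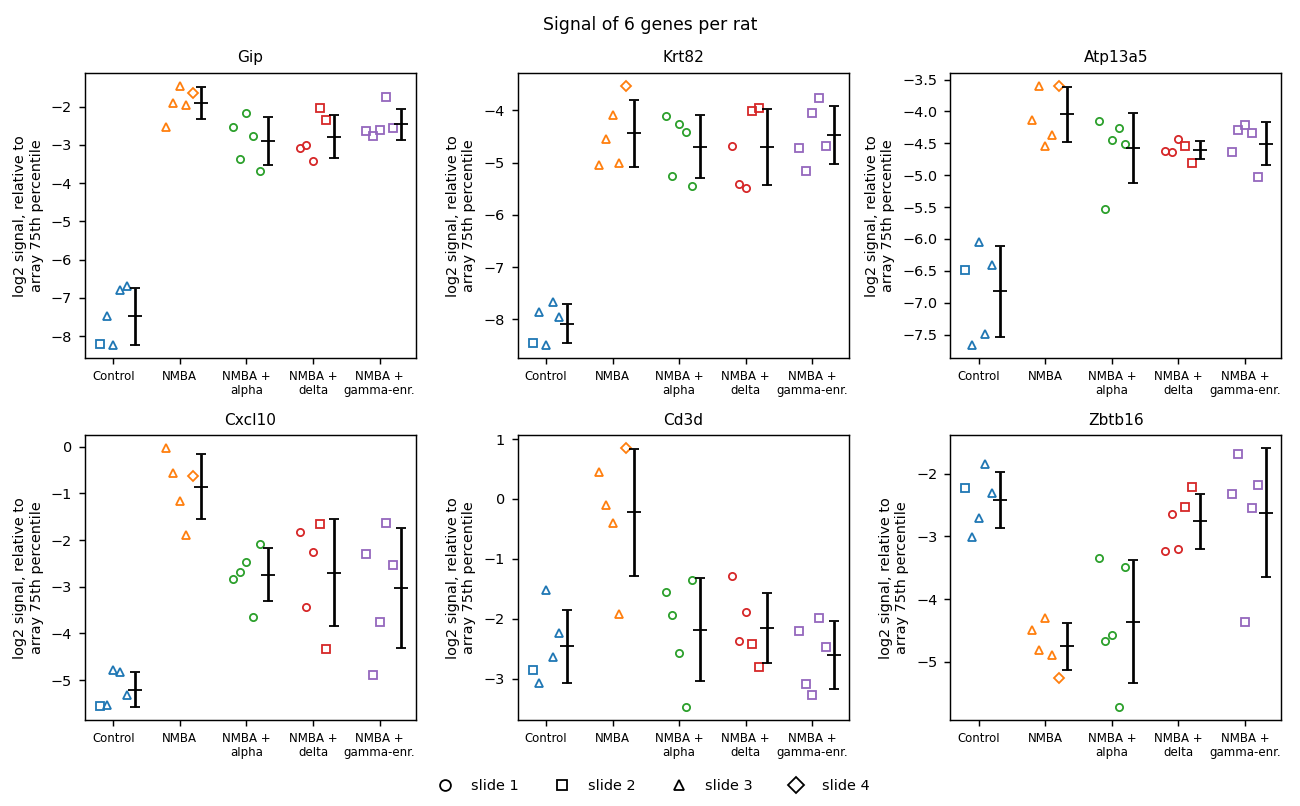
Log2 signal of Gip, Krt82, Atp13a5, Cxcl10, Cd3d and Zbtb16 in each rat (points, with symbols for the slides), with the mean and SD of each group (n = 5), relative to each array's 75th percentile. Gip, Krt82 and Atp13a5 stay above Control in the tocopherol groups, while Cd3d lies lower than in NMBA.

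Among the largest falls from Control with alpha were Zbtb16 (−1.94 ± 0.42), the co-chaperone Fkbp5 (−1.79 ± 0.36), the oxidase Cyp1a1 (−1.70 ± 0.29) and the Gip receptor Gipr (−1.63 ± 0.33); Bmp3 rose by 2.12 ± 0.31. Fgf13 rose by 1.89, 1.92 and 1.805 (± 0.26 each) in alpha, delta and gamma-enriched, and by 1.78 ± 0.26 with NMBA alone. Delta rats had lower Cfap68 (−0.94 ± 0.13) and Capn9 (−0.93 ± 0.17). Gamma-enriched rats had lower glial Gfap (−2.14 ± 0.48, at least 2.72-fold), the netrin receptor Dcc (−1.83 ± 0.39, at least 1.27-fold), Gdf2 (−1.68 ± 0.31, at least 2.66-fold), Cyp1a1 (−1.54 ± 0.29) and the clock gene Per1 (−1.18 ± 0.23), and higher Xkr4 (2.24 ± 0.41). With normexp Bmp3 stood at 0.96 and Xkr4 at 0.86, and Capn9 (−0.39), Gfap (−0.96), Dcc (−0.58) and Gdf2 (−0.73) did not pass; nor did Capn9 with quantile normalization (−0.80). The tocopherol transfer gene Ttpa rose by 1.06 ± 0.25 with alpha and 1.11 ± 0.25 with gamma-enriched. Of these genes, Cyp1a1, Gipr, Capn9, Gfap, Dcc, Gdf2, Per1 and Ttpa were not called between NMBA and Control. Interferon scores stood 0.08 (−0.19 to 0.34), 0.14 (−0.14 to 0.50) and 0.06 (−0.36 to 0.41) from Control in alpha, delta and gamma-enriched, and the CXCR3 list, not independent evidence, 0.92 (0.39 to 1.38), 0.80 (0.09 to 1.36) and 0.57 (−0.31 to 1.31). Blocked by slide, the interferon differences were −0.220, −0.0272 and 0.0954 and those of CXCR3 were 0.591, 0.729 and 0.874, with intervals that include 0. Camera with the block called skeletal muscle genes as higher than in Control in alpha, delta and gamma-enriched (adjusted p = 0.0168, 0.00111 and 0.0315). It called macrophage genes as lower in alpha too (adjusted p = 0.0168). With an estimated correlation camera's adjusted p for these was from 0.742 to 0.803. Without the block camera called none of these, and the alpha and gamma-enriched means of skeletal muscle lay below that of Control. Control rat 1, which links the slides, scored −0.779 in skeletal muscle, against −0.302 or more in the other Controls. Under that block camera called MHC class II genes as lower than in Control in alpha, delta and gamma-enriched (−0.745, −0.567 and −0.384; adjusted p = 0.044, 0.0269 and 0.0315) and T and NK cell genes in alpha (−0.600; adjusted p = 0.044), but with an estimated correlation adjusted p was from 0.709 to 0.803, and the intervals of these shifts include 0.

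Camera called 3, 6 and 10 lists against Control in alpha, delta and gamma-enriched, and with an estimated correlation each lost its call. The p53 list was higher in each group, by 0.23, 0.20 and 0.22 (adjusted p = 0.0276, 0.00823 and 0.00522, but adjusted p = 0.426, 0.274 and 0.215 with an estimated correlation), with 0 of 18 members called and 1, 0 and 0 adjusted over the list alone, and by 0.429 (0.202 to 0.656), 0.343 (0.148 to 0.538) and 0.273 (0.0987 to 0.448) with slide as a block, where camera no longer called it in alpha (adjusted p = 0.0557). Cell cycle genes were higher by 0.40 with delta, all 30 positive, and by 0.36 with gamma-enriched, 28 of 30 positive (adjusted p = 7.96e-08 and 1.19e-05, but adjusted p = 0.782 and 0.709 with an estimated correlation), with 1 of 30 called in each and 2 and 1 adjusted over the list alone; without Control rat 4 these were 0.26 and 0.23. Fibroblast matrix genes were lower, at −0.47 with delta and −0.72 with gamma-enriched (adjusted p = 5.56e-04 and 1.25e-05, but adjusted p = 0.854 and 0.709 with an estimated correlation), with 0 of 15 called and 0 and 9 adjusted over the list alone; without gamma-enriched rat 3, which scored −1.50, the latter was −0.43. Blocked by slide, these shifts were 0.648 (−0.0864 to 1.38) and 0.561 (−0.0954 to 1.22) for the cell cycle and −0.507 (−1.57 to 0.560) and −0.631 (−1.58 to 0.324) for fibroblast matrix. Lists that were lower in 1 or more groups were xenobiotic metabolism (−0.29, −0.25 and −0.34; adjusted p = 0.0276, 0.0428 and 0.0455, but adjusted p = 0.463, 0.782 and 0.709 with an estimated correlation) and, in alpha alone, nerve genes (−0.52; adjusted p = 0.0338, but adjusted p = 0.692 with an estimated correlation), at −0.30 without alpha rat 4. In delta and gamma-enriched these were macrophages (−0.37 and −0.50; adjusted p = 0.0428 and 0.0345, but adjusted p = 0.854 and 0.766 with an estimated correlation) and mast cells (−0.70 and −1.23; adjusted p = 0.0428 and 0.0133, but adjusted p = 0.854 and 0.745 with an estimated correlation). In gamma-enriched alone they were B and plasma cells (−0.73; adjusted p = 0.0248), smooth muscle (−0.59; adjusted p = 0.0181) and matrix proteases (−0.42; adjusted p = 0.0416), but adjusted p = 0.709, 0.745 and 0.745 with an estimated correlation. Without gamma-enriched rat 3 the shifts of macrophages, mast cells, smooth muscle and matrix proteases in that group were −0.14, −0.79, −0.385 and −0.28. Under the slide block, B and plasma cells stood at −0.222, smooth muscle at −0.228 and matrix proteases at −0.318 in gamma-enriched, nerve genes at −0.519 in alpha, and xenobiotic genes at −0.321 in alpha and −0.259 in delta, and camera no longer called them (adjusted p from 0.105 to 0.311). Xenobiotic genes in gamma-enriched, at −0.333, and macrophages and mast cells, at −0.750 and −1.118 in delta and −0.582 and −1.133 in gamma-enriched, were still called with the block, but adjusted p was from 0.663 to 0.763 with an estimated correlation. EGFR ligands were higher there by 0.21 (adjusted p = 0.0416, but adjusted p = 0.709 with an estimated correlation) and stood at 0.0464 with slide as a block, where camera's direction turned. With slide as a fixed block 4 genes were called against Control in each group, Gip, Krt82, Fgf13 and Plpp1, of which Plpp1 and, outside delta, Fgf13 were named after their values were seen. The Plpp1 calls rest on the low value of Control rat 1. Without the block Plpp1 stood at 0.50, 0.61 and 0.45 (± 0.46 each) and did not pass. Of the calls, 87.5% were higher for delta, and 37 of 54 with normexp; 57.7% were higher for gamma-enriched, and 48 of 69 with quantile normalization and 21 of 25 with normexp. The alpha count fell to 36 without alpha rat 1, 61 without alpha rat 4, 67 without Control rat 3, 25 without Control rat 4 and 32 without Control rat 5. The delta count fell to 15 without delta rat 5 and to 15 without Control rat 4, and rose to 81 without Control rat 1. The gamma-enriched count fell to 32, 35 and 39 without gamma-enriched rats 1, 2 and 5, and to 51, 40, 25 and 27 without Control rats 2, 3, 4 and 5, and rose to 697 without Control rat 1.

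The preparations were compared with each other, since they are related molecules. Delta differed from alpha in 0 genes by limma (571 at an unadjusted p under 0.05, against 617.2 by chance), and gamma-enriched from delta in 0 (503 unadjusted). Interferon scores differed by 0.06 (−0.28 to 0.48) for delta minus alpha, −0.02 (−0.52 to 0.41) for gamma-enriched minus alpha and −0.08 (−0.57 to 0.39) for gamma-enriched minus delta. T and NK cell scores differed in the same order by −0.008 (−0.63 to 0.62), −0.17 (−0.82 to 0.45) and −0.17 (−0.80 to 0.52), MHC class II scores by −0.05 (−0.53 to 0.46), −0.20 (−0.64 to 0.28) and −0.15 (−0.61 to 0.32), and CXCR3 scores by −0.12 (−0.95 to 0.64), −0.35 (−1.30 to 0.51) and −0.24 (−1.26 to 0.79). Without a block, camera called none of these lists between the forms. For CXCR3 the intervals of gamma-enriched minus alpha and minus delta reach the size of alpha's shift from NMBA (−1.18), whereas those of interferon, T and NK cell and MHC class II scores stay short of alpha's shifts in these lists. Within a slide the delta minus alpha differences were 0.193 for interferon and 0.261 for T and NK cells (exact permutation p = 0.357 for each), and gamma-enriched minus delta 0.123 and 0.237. Blocked by slide, gamma-enriched minus alpha was 0.315 (−0.326 to 0.957) and 0.499 (−0.448 to 1.45). With that block camera called both lists as higher in delta than in alpha (adjusted p = 0.0134 and 0.0374) and in gamma-enriched than in alpha (adjusted p = 0.0201 each), and NF-κB targets, not independent evidence, as higher in delta than in alpha (0.362, −0.269 to 0.992; adjusted p = 0.0134), but adjusted p was 0.975 or more with an estimated correlation.

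Gamma-enriched differed from alpha in 200 genes, 20 higher and 180 lower. The clock gene Per2 fell by 2.71 ± 0.64 and Per1 fell by 1.03 ± 0.23. The stress-response phosphatase Dusp1 fell by 1.18 ± 0.20 and the B cell gene Cd79b fell by 1.45 ± 0.36, at least 1.32-fold. The olfactory receptor genes Or4a47 (−2.55 ± 0.41, at least 1.69-fold) and Or11g24 (−2.11 ± 0.43, at least 2.07-fold) and the kinase Tnni3k (−2.11 ± 0.37, at least 1.48-fold) were also lower. Stfa3l1 rose by 1.89 ± 0.38, the glutathione transferase Gstm6 by 1.82 ± 0.43 and Gipr by 1.38 ± 0.33. With normexp Or4a47 stood at −1.09 and Or11g24 at −0.78, and Gipr (1.04) and Tnni3k (−0.70) did not pass. Of the 180 lower genes, 166 were among the dimmest 4115 of the genes tested. No slide holds both groups. In all, 66 genes were called with normexp, 6 with only probes above background on all 25 arrays, and 0 with slide as a fixed block by limma (742 at an unadjusted p under 0.05). The count fell to 47, 46 and 24 without alpha rats 1, 2 and 5 and to 66, 33, 97 and 77 without gamma-enriched rats 1, 2, 4 and 5, and rose to 556 without alpha rat 4. Camera called 0 lists in gamma-enriched against alpha or delta (4 and 7 unadjusted; fry 0 in each, 2 and 0 unadjusted), and 1 in delta against alpha, cell cycle genes at 0.24 (adjusted p = 1.66e-04, but adjusted p = 0.973 with an estimated correlation), which moved to 0.11 without alpha rat 3 and 0.37 without alpha rat 4. Blocked by slide it was 0.201 (−0.236 to 0.639). With that block camera called skeletal and smooth muscle genes as lower in gamma-enriched than in delta (adjusted p = 0.00446 and 0.00508). It also called nerve and Schwann cell genes as higher in delta than in alpha (adjusted p = 0.0134). With an estimated correlation camera's adjusted p was 0.909 for the muscle lists and 0.98 for nerve.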

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

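Chosen only after the results they measure were seen were the tests of slide on the immune genes, of NMBA rats 2 and 3, of slide 2 against slide 1 and against the other slides, and of the dim end of the signal.

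Immune gene expression was lower in the tocopherol groups than in NMBA, by 1.02 log2 units over the T and NK cell, interferon, MHC class II and CXCR3 members together. Without NMBA rats 2 and 3, which had few spots above background, the difference was −0.979 (−1.44 to −0.50; exact permutation p = 0.00245 over 816 assignments), an interval that excludes 0 but leaves a partial contribution of these rats open. A slide effect also stays open: with slide as a fixed block the difference was −1.10 (−1.95 to −0.264), but this rests on Control rat 1 as the only link between the slides. Control rat 1 stood at −0.268 in T and NK cells, −0.282 in interferon, 0.0857 in MHC class II and −1.18 in CXCR3, against means of −0.239, −0.235, −0.155 and −0.798 in the other Controls. The means of delta rats on slide 2 lay below those on slide 1 in each list (−0.607 against 0.0665, −0.309 against 0.0303, −0.482 against 0.0793 and −0.454 against 0.178). Only in CXCR3 did these rats overlap, with delta rat 4 on slide 2 at 0.0949 and delta rat 2 on slide 1 at −0.246. A tocopherol effect, which the design names, may explain the same values and was not tested separately from slide.

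The many genes lower in the gamma-enriched group form the second pattern. In the 180 genes lower than in alpha (median −1.45), delta rats 4 and 5 and Control rat 1, which share slide 2 with the gamma-enriched rats, lay −0.916 from their group mates on other slides (−0.627, −0.523 and −1.60 singly), the lowest of 50 choices of such arrays (exact permutation p = 0.02). Delta rats alone, slide 2 minus slide 1, gave −0.561, and the dimmest genes as a class −0.162 with 31.1% of the calls kept under normexp, so a slide 2 effect at the dim end is a candidate explanation for part of the difference. In the 909 genes lower than in NMBA (median −0.99) the slide 2 arrays lay at −0.325 (exact permutation p = 0.06), with −0.130, −0.158 and −0.687 singly, which leaves both slide and treatment open. No gene was called between gamma-enriched and alpha with slide as a block (0 by limma, 742 at an unadjusted p under 0.05), and an effect of gamma-tocopherol remains among the open explanations.

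Other splits of the same rats were counted for each comparison, over 100 splits of 10 rats into 5 and 5. The mark set in advance was fewer than 5 splits as large, the real one included, without adjustment over the comparisons. For NMBA against Control 2 were as large (real 191, highest other 911), so the mark was met but another grouping gave more genes. The higher split put NMBA rats 1, 2 and 5 with Control rats 2 and 3. These arrays lie in columns 1 and 2 of their slides and the other 5 in columns 3 and 4, so this split follows array position; with the column as a covariate NMBA against Control gave 254 genes. For alpha, delta and gamma-enriched against NMBA 1, 1 and 2 splits were as large, so the real count was the highest for alpha and delta only. The real counts were 471, 307 and, for gamma-enriched, 196 higher and 909 lower genes, and the highest others were 134, 274 and 2220. The last of these exchanged gamma-enriched rat 3 and NMBA rat 4, and it too points to a structure of the samples. Against Control, 1, 1 and 3 splits were as large for alpha, delta and gamma-enriched (real 101, 24 and 78, highest others 65, 4 and 980). Here too the real count was the highest for alpha and delta only. The split with 980 genes set Control rat 1 with gamma-enriched rats 1, 2, 4 and 5, all on slide 2, and so follows that slide; with slide as a block 4 genes were called. For gamma-enriched against alpha 4 splits were as large (real 200), which met the mark narrowly. Where another grouping gave more genes, the splits do not exclude chance. The highest other, 864, exchanged gamma-enriched rat 4 and alpha rat 4 and points to a structure of the samples. It put alpha rat 4 with gamma-enriched rat 3, each with the lowest T and NK cell score of its group (−0.817 and −1.14). Their fibroblast matrix (−0.610 and −1.50) and mast cell scores (−1.44 and −2.40) were also the lowest. NMBA rat 5, low in fibroblast matrix genes (−1.08), had a high T and NK cell score (1.30). Whether tissue content differed between rats was not tested. For delta against alpha and gamma-enriched against delta the real count was 0 (by limma; 571 and 503 unadjusted), which no split can fall below, so the splits say nothing about them (highest others 5 and 8).

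Single rats stood far from the other 4 of their group in 51 of 585 groups examined, over 96 genes and 20 list scores named in the text and the share of spots above background; chance gives about 1 in 20. Control rat 1, the only Control on slide 2, accounted for 9 of them. Plpp1 was called with slide as a block. That block takes the offset between the tocopherol and NMBA slides from this rat against the other Controls, so the call rests on its value. Control rat 1 had Plpp1 at −1.92 against 1.43 or more in the other Controls. It also had low Or11g24 (−8.85), Tnni3k (−8.58), Cxcl11 (−6.02), Zbtb46 (−5.34), Krt13 (4.42) and Cnfn (3.99), a low squamous differentiation score (−0.259) and high Trib1 (−4.84). NMBA rat 5, alone on slide 4, had low fibroblast matrix (−1.08) and smooth muscle (−0.825) scores and low Plpp1 (0.338).

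Alpha rat 4 had high Bub1 (−0.376), Pds5a (−4.31), Pkn2 (−2.60) and Tyms (−0.984), and low Gzmb (−6.38) and Aif1 (1.05). Gamma-enriched rat 3 had high Ccnd1 (2.22), Nqo1 (3.73) and Notch1 (2.15), and low Ciita (−3.47) and Col1a1 (1.18). NMBA rat 4 had low squamous differentiation (−0.0805) and B and plasma cell (−0.327) scores, Cd79b (−6.76) and Tgm1 (3.37). Alpha rat 1 had high Cd8b (−5.64) and low Gstm6 (−5.04) and Stfa3l1 (−6.25), and alpha rat 2 had low Atp13a5 (−5.53), Trib1 (−5.15) and Ptger4 (−5.92). In alpha rat 5 Myh3 (−2.60) and Pdk4 (−1.11) were high. Delta rat 1 had high Asic3 (−7.38) and Zbtb46 (−4.17), delta rat 2 low Gstm6 (−4.24), delta rat 3 a low squamous differentiation score (−0.302) and low Krt14 (4.11), and delta rat 4 high Ccl12 (−5.65) and low Phactr3 (−6.003). Low values were found for Ccnd1 (1.52) and Phactr3 (−5.67) in Control rat 2, for Hmmr (−4.91) and the macrophage score (−0.0509) in Control rat 4, and for Pkd2l2 (−8.44) in NMBA rat 1. Gamma-enriched rat 2 had low Cd79b (−9.35) and a low B and plasma cell score (−1.01), and gamma-enriched rat 4 had high Gip (−1.76) and Gria2 (−6.04).

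Outside the named genes, 56 of 8538 probes without a gene name changed between NMBA and Control, 43 higher and 13 lower, by limma.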

How the results depend on the processing

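Chosen after seeing the data were the tests without NMBA rats 2 and 3, gamma-enriched rat 3 or the slide 4 array, with the slide column, and with all probes; normexp on mean signals was not run, since the scanner files hold none, and median signals took their place. Comparisons are given as group against reference, and a change of direction is counted only where one of both values passed the test. Over 389 values of named genes, 361 kept their direction and side of the threshold with quantile normalization, 343 with normexp and 381 with the authors' value table. With no filter 366 did, with the mean of probes 379, with rat number as a block 359 and with the slide column 360. Without gamma-enriched rat 3 it was 365, and without the slide 4 array 350. The lowest were 314 with only the groups compared, 285 without NMBA rats 2 and 3, and 231 with slide as a fixed block. With that block 150 no longer passed and 8 turned, namely Ptger4 (−0.20) and Pkm (0.0095) for alpha against NMBA, Asic3 (0.64) and Krt4 (0.0099) for delta, and Pkn2 (−0.0233), Sslp1l1 (0.38), Zbtb46 (0.0843) and Mmp13 (0.29) for gamma-enriched. The 389 values include those that the main fit did not call. Of the 183 called values of named genes, 158 no longer passed with slide as a fixed block, 104 without NMBA rats 2 and 3, and 72 with only the groups compared. Normexp made 56 of the 183 over 1.5 times smaller, quantile normalization 12 and the mean of probes 5. Slide as a fixed block made 52 over 1.5 times smaller and 11 over 1.5 times larger. Counts of 0 between delta and alpha and between gamma-enriched and delta stayed at 0 by limma in each setting run.

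Slide as a fixed block gave 62 genes for NMBA against Control, 1, 1 and 1 for alpha, delta and gamma-enriched against NMBA, 4, 4 and 4 against Control and 0 for gamma-enriched against alpha. It gave a share of opposite changes of 79.0% for alpha and 80.7% for delta. This block leaves 1 array to link the tocopherol and NMBA slides, which widens the errors. Slide 3 alone, with 8 arrays, gave 31 for NMBA against Control. As a random block, slide gave 800, 742 and 1805 against NMBA, 312, 51 and 308 against Control and 440 for gamma-enriched against alpha. Its estimated correlation was negative (−0.0311), which lowers the errors of comparisons between slides. Groups and slides largely coincide, so these higher counts do not show that the calls withstand a slide effect. The slide column gave 1003, 1055 and 1788 against NMBA and 205, 80 and 658 against Control. Rat number as a replicate block gave 310 and 161 for alpha and delta against NMBA, 52 and 34 for alpha and gamma-enriched against Control and 111 for gamma-enriched against alpha; same-number rats did not resemble each other. For the blocks and the covariate, causes beyond the lost links and the negative correlation were not tested.

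Without NMBA rats 2 and 3, counts were 63 for NMBA against Control with 11 lists, 22, 0 and 156 for alpha, delta and gamma-enriched against NMBA (by limma; 1552 unadjusted for delta), and 40 for gamma-enriched against Control, from fewer arrays. Without gamma-enriched rat 3 delta against NMBA gave 511, and without the slide 4 array NMBA against Control gave 96. Fits on only the groups compared, with fewer arrays, gave 95 for NMBA against Control, 114 and 71 for alpha and delta against NMBA, and 6 and 19 for alpha and gamma-enriched against Control. Normexp gave 164, 54 and 25 against Control and 66 for gamma-enriched against alpha, and the cause was not tested. With no filter, alpha, delta and gamma-enriched against NMBA gave 2141, 961 and 3321, with 3 lists for alpha. A filter on all 25 arrays gave 691 for gamma-enriched against NMBA, 33 against Control and 6 against alpha, with fewer genes tested. All probes, with more features tested, gave 1070, 644 and 1909 against NMBA, 165, 54 and 126 against Control and 428 for gamma-enriched against alpha.

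Leaving out each rat in turn gave 96 to 297 genes for NMBA against Control, 191 to 454, 13 to 566 and 546 to 1588 for alpha, delta and gamma-enriched against NMBA, 25 to 111, 15 to 81 and 25 to 697 against Control, and 24 to 556 for gamma-enriched against alpha. Lists ran from 7 to 9 for NMBA against Control and from 5 to 8, 4 to 7 and 5 to 7 for alpha, delta and gamma-enriched against NMBA. Delta against alpha and gamma-enriched against delta stayed from 0 to 0 by limma. Between 70.6% and 79.8% of spots were well above background, so the dimmest genes are the least certain.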

Other observations

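Some genes outside the main lists also changed with NMBA. The stromelysin Mmp10 rose by 1.80 ± 0.31 with NMBA alone and stood 1.61 ± 0.31, 1.41 ± 0.31 and 1.34 ± 0.31 from Control with alpha, delta and gamma-enriched, of which delta did not pass (limma adjusted p = 0.0605). The surfactant gene Sftpc rose by 1.03 ± 0.17 with NMBA, 1.23 ± 0.17 with alpha and 1.08 ± 0.17 with delta, and at 0.69 ± 0.17 with gamma-enriched did not pass. The list of neighbouring respiratory and thyroid tissue that holds it stood at −0.41 in NMBA (−1.53 to 0.64; camera adjusted p = 0.951), so its rise was not that of the list. Notch1 rose by 0.86 ± 0.18 and the amino acid stress gene Asns by 0.92 ± 0.18, and Wnt5a fell by 1.53 ± 0.39. Blocked by slide these stood at 1.47 for Mmp10, 1.01 for Sftpc, 0.78 for Notch1, 0.81 for Asns and −1.58 for Wnt5a, of which Mmp10 and Sftpc still passed. With normexp Mmp10 (0.69) and Sftpc (0.64) were smaller and Wnt5a (−0.94) did not pass.

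In the gamma-enriched group relative to NMBA, the macrophage genes Aif1 and C1qa fell by 1.02 ± 0.25 and 0.90 ± 0.28, and the basal keratin Krt14 fell by 0.74 ± 0.17. Blocked by slide these stood at −0.75, −0.62 and −0.12, none past the test. With quantile normalization C1qa (−0.55) and Krt14 (−0.095) did not pass either. Under the slide block camera called the macrophage list as lower than in NMBA in alpha, delta and gamma-enriched (−0.933, −0.899 and −0.731) and skeletal muscle genes as higher (1.44, 1.42 and 0.802), with adjusted p of 0.00294 or less, but from 0.753 to 0.812 with an estimated correlation; the intervals of these shifts include 0. Without the block camera called neither the macrophage nor the skeletal muscle list against NMBA, and the gamma-enriched mean of skeletal muscle lay below that of NMBA. Control rat 1, which links the slides, scored −0.779 in skeletal muscle, against −0.302 or more in the other Controls. The vitamin E handling list did not differ by camera in the comparisons with NMBA or Control. Its score in gamma-enriched rats stood −0.32 from Control (−0.69 to −0.02; exact permutation test, adjusted p = 0.143), and −0.20 without gamma-enriched rat 3, while its member Ttpa was higher.

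One hypothesis was tested, with a list of glucocorticoid-induced genes drawn up after Fkbp5, Zbtb16, Pdk4 and Cyp2b2 had been seen; those 4 members were left out. Fkbp5 (−1.58 ± 0.36) and Zbtb16 (−2.33 ± 0.42) were lower with NMBA, which less glucocorticoid action could explain, and Cyp2b2 stood at −1.53. The 16 other members stood at a mean of −0.140 (−0.40 to 0.10, exact permutation p = 0.246) and ran from −0.94 (Klf15) to 0.63 (Mt1). Fkbp5 and Zbtb16, with a mean of −1.96, had been picked for their falls, so a class mean near theirs was unlikely from the start. The test therefore argues only against a fall of the class near that size. A weaker effect, or one confined to some target genes, stays open.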
